A study of Simmondsia chinensis with 44 samples.

How the data were processed

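Gene expression was measured by RNA sequencing in 44 jojoba seed libraries, 24 from a time course of seeds and 20 from mid-stage seeds that were dissected or left whole. Per the labels, RNA was extracted with a hot-borate method and libraries were made with a stranded mRNA kit, which selects polyadenylated RNA. Single tissues that the design text mentions beside the seeds were not analysed here. Per the submitters' processing notes, the tools included Trimmomatic, STAR and DESeq2, with no versions. The counting step, the genome build, the annotation and the use of strand in counting are not given in the sources used here.

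The deposited files hold whole-number read counts per gene, not normalized, in 1 table for the time course and another for the dissection series, each over 23491 genes. The authors also deposited the same tables normalized, and these values were treated as a signal relative to library size. In each library the count divided by the normalized value was 1 factor for all genes, with a largest relative deviation of 5.86e-10 in the time course and 6.24e-10 in the dissection series. The factors matched DESeq2's median of ratios, recomputed from the counts within each table, to within 4.69e-11 and 2.44e-11. The normalized tables therefore held no value apart from the counts, the tables were normalized separately, and all tests ran on the counts and within 1 table. Every per-sample column was matched to its library by the name the labels give.

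Libraries were grouped by stage and tissue as the titles state. The titles do not say whether the time-course seeds, dry seeds included, kept their seed coat. No libraries of a group agreed within sampling noise (lowest chi-square per degree of freedom 8.84 and 10.9), so none was counted as a duplicate. Total counts per library ranged from 7713214 to 23773845 in the time course, where dry seed was the deepest stage, and from 9882334 to 32758764 in the dissection series. A count of 0 was read against a floor of 3 counts per library. Intervals on pooled count ratios are 95% intervals, and intervals and floors cover counting error only.

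The main test was edgeR 4.0.16 (R 4.3.3), with TMM normalization, filterByExpr at its defaults, estimateDisp, glmQLFit and glmQLFTest. All 4 groups of a table entered 1 fit, and 7 comparisons were read as contrasts from it, with Benjamini-Hochberg adjustment and a threshold of 0.05. The filter left 18440 genes in the time course and 18499 in the dissection series. Changes of at least 2-fold are counted beside each total, from the fitted log2 fold change. Gene sets were tested with camera in limma 3.58.1 on voom values, with a preset correlation of 0.01, and adjusted over the 9 set tests of the time course and the 12 of the dissection series. Set medians used log2 of TMM CPM plus 0.5. The share of counts in the 100 most counted genes and the genes detected at 1 CPM were compared by two-sided exact permutation tests of the difference of means, adjusted over 6 pairs. Whole-seed profiles were fitted on the mean profiles of the 3 dissected parts by non-negative least squares in scipy 1.17.1, with each gene divided by the square root of its mean TMM CPM, and shares scaled to sum to 100%. A form of these weights taken from each whole-seed library was tried before and replaced, after its shares were seen, by the planned form. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and plots.

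Named genes followed a rule fixed before the data were examined. With identifiers that the files do not pair with names, it takes the 2 genes with the largest rise and the 2 with the largest fall in each comparison. Eligible genes had an adjusted p under 0.05, a mean of at least 10 CPM in the higher group and groups whose libraries do not overlap. Lists of genes for wax ester, fatty acid and storage protein metabolism had been planned and were not used, since they need names. Near-identical gene copies may share reads, and antisense overlap may add reads if strand was not used in counting, so values of single genes are uncertain to that extent.

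The alternatives fixed before the data were examined were DESeq2 1.42.0 with its Wald test, DESeq2's size factors or upper-quartile scaling in the edgeR fit, no filter, the replicate number as a block, only the 2 groups compared, and each library left out in turn. For sets they were an estimated correlation, a 2-fold threshold and fry. Camera tests a set against the other genes and fry tests it against no change, so a pass by fry does not contradict camera. For the library measures they were 10 or 1000 genes, a fixed list of 100 genes, 5 CPM, and 10 counts after thinning. Thinning all libraries of a table to its smallest total, leaving out cotyledon libraries 1 and 5, and leaving out late-seed libraries 4 and 6 were added after seeing the data. Other splits of the libraries were drawn with a fixed seed, 40 per comparison, a number lowered for computing time after a longer draw for the time course had been seen. The edgeR steps were tested on simulated counts for the real genes and library sizes, with 200 genes changed. For mid against early seed over 18440 genes, 32.1% of genes changed 1.5-fold, 66.4% changed 2-fold and 94.7% changed 4-fold were recovered. For cotyledon against axis over 18499 genes the shares were 24.6%, 54.5% and 88.6%. False calls were 4.10% and 1.30% of calls. Far more genes differed in the real comparisons, so these shares may not carry over to them. The mixture fit recovered 3 simulated mixtures over 18499 genes to within 0.0797 percentage points. These mixtures were drawn from the same mean profiles that were fitted, with counting noise only. They test the computation and not the accuracy of the shares in real whole seed.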

Results

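Jojoba (Simmondsia chinensis) is a desert shrub whose seeds store liquid wax esters in place of the usual seed oil. Gene expression was measured by RNA sequencing in 44 libraries from seeds of one germplasm line. A time course held early, mid, late and dry seed, with 6 libraries each. A dissection series held cotyledon, embryonic axis, seed coat and whole seed of the mid stage, with 5 libraries each. Total counts ranged from 7713214 to 16014089 in early, mid and late seed, from 15658880 to 23773845 in dry seed and from 9882334 to 32758764 in the dissection series. Both series were counted over 23491 genes, and levels are given as CPM, counts scaled to TMM-adjusted library totals, while shares of counts and genes detected are taken without TMM scaling. The files do not pair the gene identifiers with names or functions, so genes are given by identifier only, with at most 2 that rose and 2 that fell in each comparison. The labels do not say whether libraries of one group came from separate plants or seeds, so all p-values measure the spread between these libraries, which may be technical.

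Libraries grouped by stage, and by tissue except for cotyledon, whose libraries were spread out. In the time course the first principal component took 68.2% of the variance and set dry seed apart from the other stages, and the second took 16.0% and ordered early, mid and late seed. In the dissection series the first component took 55.3% and set seed coat apart from the embryonic tissues, and the second took 17.01% and parted cotyledon from axis. Whole seed lay between seed coat and cotyledon. Cotyledon libraries 1 and 5 lay nearest to whole seed among the cotyledon libraries, and late-seed libraries 4 and 6 lay nearest to dry seed among the late-seed libraries.

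**Figure D1:**
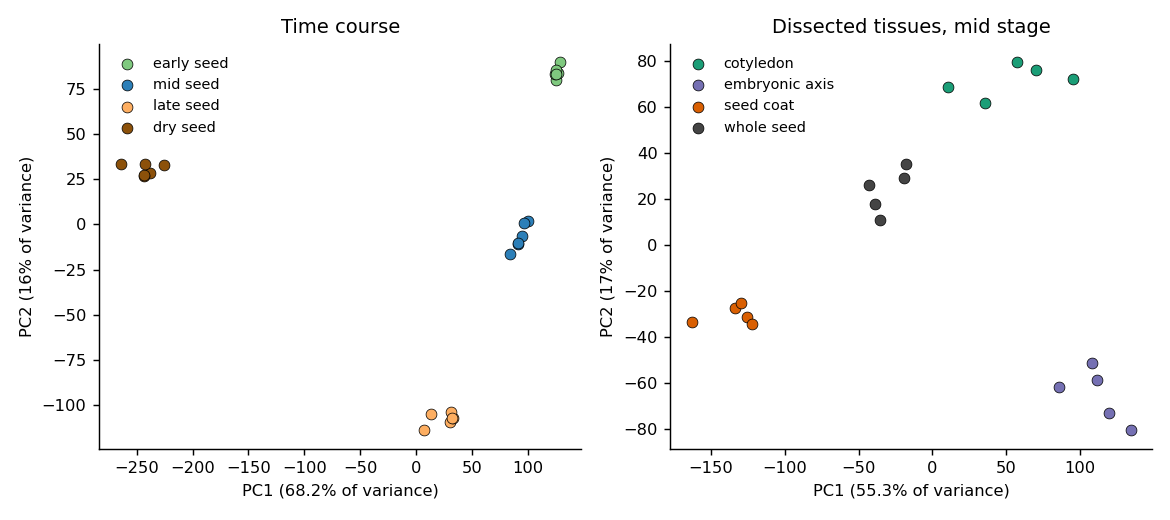
Principal components of log2 CPM for the time course (left, 6 libraries per stage) and the dissection series (right, 5 libraries per tissue), 1 point per library. The first axis takes 68.2% and 55.3% of the variance. Cotyledon library 5 lies nearer to whole-seed library 4 than to cotyledon libraries 2, 3 and 4.

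Sets of tissue-preferred genes were taken from the dissection series and followed through the time course, and stage-preferred genes from the time course were followed through the tissues. A gene was tissue-preferred when it was at least 4-fold higher in one dissected tissue than in each of the others, at an adjusted p under 0.05 by edgeR's quasi-likelihood test. This gave 231 cotyledon-preferred, 541 axis-preferred and 619 coat-preferred genes. The same rule over the stages gave 270 early-preferred, 69 mid-preferred, 158 late-preferred and 981 dry-preferred genes. The camera tests of each set used libraries other than those that defined it. Set against other splits of the same libraries, 2 of the 21 set results below had a smaller camera p than every other split drawn. They were the rise of cotyledon-preferred genes into mid seed and the fall of coat-preferred genes into dry seed. In the other 19, other splits gave a p as small. With 40 splits and no adjustment over the 21 results, this does not exclude chance for any of them. The fall into dry seed was also lost at adjusted p = 0.0535 with an estimated correlation in limma's camera. Counts of members that rose or fell moved by at most 6 genes when adjusted over the list alone.

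From early to mid seed, most cotyledon-preferred genes rose, and more coat-preferred genes fell than rose. By camera in limma the rise of the cotyledon-preferred set passed (adjusted p = 1.91e-08, and adjusted p = 0.0273 with an estimated correlation), and the fall of the coat-preferred set passed (adjusted p = 1.28e-07) but was lost at adjusted p = 0.217 with an estimated correlation. Of 212 cotyledon-preferred genes measured, 123 rose and 34 fell, and their median level went from 1.40 ± 0.22 to 2.63 ± 0.12 on the log2(CPM + 0.5) scale (SD, n = 6). Of 574 coat-preferred genes, 81 rose and 269 fell, and their share of counts went from 11.3% ± 1.8 to 6.49% ± 1.16 (SD, n = 6). Without the most counted member, Sc18g0006960, that share went from 6.39% ± 1.03 to 4.21% ± 0.89. Of 357 axis-preferred genes, 89 rose and 114 fell. Sc03g0002620 stood at 523 ± 295 CPM in mid seed and 0.155 ± 0.231 in early seed (SD, n = 6), a log2 change of 11.64 ± 0.87 (SE).

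Across all genes, 9142 of 18440 tested differed between mid and early seed by edgeR's quasi-likelihood test at an adjusted p under 0.05, 4798 higher and 4344 lower in mid seed. That balance is not firm: it turned with DESeq2 size factors (4323 and 4970), upper-quartile scaling (4135 and 5217), DESeq2's Wald test (4572 and 5302), no filter (4476 and 5048), only the 2 groups compared (4828 and 4972) and without mid-seed library 4 (4083 and 4631). At least 2-fold, 1893 were higher and 1707 lower. Sc14g0002460 rose from 1 count in all early libraries together to 75.4 ± 22.7 CPM, a pooled ratio of 5983 with a 95% counting interval of 1073 to 236350 (edgeR adjusted p = 1.50e-13). Sc09g0001520 fell, with a log2 change of -8.39 ± 1.06, and Sc13g0002850 fell, with -7.91 ± 1.11 (SE, edgeR adjusted p = 6.10e-07 and 3.44e-05). Single libraries moved these values. The change of Sc09g0001520 was -6.78 without early-seed library 6, that of Sc13g0002850 was -6.99 without early-seed library 6 and -8.97 without mid-seed library 2, and that of Sc03g0002620 was 12.81 without early-seed library 2. By camera the axis-preferred set did not pass (adjusted p = 0.113). By fry, which tests against no change and not against the other genes, it was lower (adjusted p = 5.64e-04). Genes detected at 1 CPM or more went from 17276 ± 161 in early seed to 17038 ± 122 in mid seed (SD, n = 6; exact permutation test, two-sided, adjusted p = 0.0286), a call lost at adjusted p = 0.0519 without early-seed library 2 or 3 or mid-seed library 5.

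From mid to late seed, more coat-preferred genes fell than rose and the late seed put a larger part of its transcripts into few genes. By camera in limma the coat-preferred set fell (adjusted p = 9.65e-08), a call lost at adjusted p = 0.217 with an estimated correlation. Of 574 coat-preferred genes, 56 rose and 308 fell, and their share of counts went from 6.49% ± 1.16 to 2.20% ± 0.16 (SD, n = 6). Without Sc18g0006960 that share went from 4.21% ± 0.89 to 1.68% ± 0.11. Cotyledon-preferred genes went both ways, with 67 rising and 74 falling of 212, and so did axis-preferred genes, with 92 rising and 139 falling of 357. The 100 most counted genes of each library took 29.8% ± 1.5 of counts in late seed and 20.001% ± 1.034 in mid seed (SD, n = 6; exact permutation test, two-sided, p = 0.00216, the smallest 6 libraries against 6 can give; adjusted p = 0.0130 over 6 tests). Sc13g0004140 rose from 4 counts in all mid-seed libraries together to 1856 ± 1628 CPM (log2 change 15.05 ± 0.82, SE; edgeR adjusted p = 4.74e-13).

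In the test across all genes, 10532 of 18440 differed between late and mid seed, 5033 higher and 5499 lower in late seed by edgeR at an adjusted p under 0.05. At least 2-fold, 1904 were higher and 2625 lower. Sc03g0009330 rose from 2 counts to 215.6 ± 149.2 CPM, a pooled ratio of 9387 (95% counting interval 2598 to 77517). Sc18g0000230 fell from 51.1 ± 36.5 CPM to 2 counts in all late-seed libraries, a pooled ratio of 1698 (470 to 14029). Sc20g0004390 fell from 17.4 ± 6.1 CPM to 1 count, a pooled ratio of 1190 (213.2 to 47031). Their edgeR adjusted p, which the naming rule asks to be under 0.05, were 1.06e-10, 1.04e-11 and 2.64e-09. By camera neither the cotyledon-preferred set (adjusted p = 0.643) nor the axis-preferred set (adjusted p = 0.334) passed. By fry, which tests against no change and not against the other genes, the axis-preferred set was lower (adjusted p = 0.00234).

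Dry seed differed from late seed in most of the genes tested. The labels do not say whether the dry seeds kept their seed coat, so levels of coat-preferred genes may reflect its absence. By camera in limma the coat-preferred set fell (adjusted p = 8.75e-16) and the cotyledon-preferred set fell (adjusted p = 1.81e-05), and both calls were lost at adjusted p = 0.0535 with an estimated correlation. Of 574 coat-preferred genes, 33 rose and 469 fell, 101 had no count in any dry-seed library, and the share of counts on the set went from 2.20% ± 0.16 to 0.286% ± 0.022 (SD, n = 6). Without Sc18g0006960 the late-seed share was 1.68% ± 0.11. Of 212 cotyledon-preferred genes, 32 rose and 145 fell, and their share went from 1.92% ± 1.07 to 0.203% ± 0.024. Without the most counted member, Sc14g0008170, the late-seed share of these genes was 1.09% ± 0.21. Of 357 axis-preferred genes, 115 rose and 159 fell, while the share of counts on the set went from 0.509% ± 0.313 to 3.28% ± 0.95. The late-seed mean was raised by libraries 4 and 6 (1.11% and 0.580%, others 0.287% to 0.381%), the ones nearest to dry seed. Sc18g0006960 and Sc18g0004510 stood at 5656 ± 873 and 4776 ± 503 CPM in late seed and had no count in any of the 6 dry-seed libraries, which made them at least 30918-fold and 26107-fold lower against a floor of 3 counts per library.

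By edgeR's test 14771 of 18440 genes, or 80.1%, differed between dry and late seed, 6795 higher and 7976 lower in dry seed. At least 2-fold, 4256 were higher and 5908 lower, and at least 16-fold, 259 were higher and 1925 lower. Sc03g0000810 rose from 2 counts in all late-seed libraries to 225.7 ± 162.0 CPM, a pooled ratio of 8459 (95% counting interval 2342 to 69856). Sc20g0000350 rose from 1 count to 83.5 ± 42.9 CPM, a pooled ratio of 5966 (1070 to 235665). The highest edgeR adjusted p of the 4 named genes, which were chosen with p as a criterion, was 7.10e-12. Genes detected at 1 CPM or more fell from 16534 ± 49 in late seed to 14711 ± 298 in dry seed (SD, n = 6; exact permutation test, two-sided, adjusted p = 0.00649). By camera, which tests a set against the other genes, the axis-preferred set did not pass (adjusted p = 0.941). By fry, which tests it against no change, the set was lower (adjusted p = 0.00395), where 80.1% of all genes differed. The median log2 change of all genes was -0.13 under TMM and -0.29 under upper-quartile scaling, so counts of higher and lower genes are relative to that shift. The share of counts in the 100 most counted genes was 27.2% ± 5.0 in dry seed, not separable from late seed (exact permutation test, two-sided, adjusted p = 0.266), but it was lower without dry-seed library 4, which had 36.2% (adjusted p = 0.00649). Dry seed was also lower for the 10 most counted genes (adjusted p = 0.00649) and for a fixed list of 100 genes (adjusted p = 0.0130), not for 1000 genes (adjusted p = 0.615, all by exact permutation test).

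**Figure D2:**
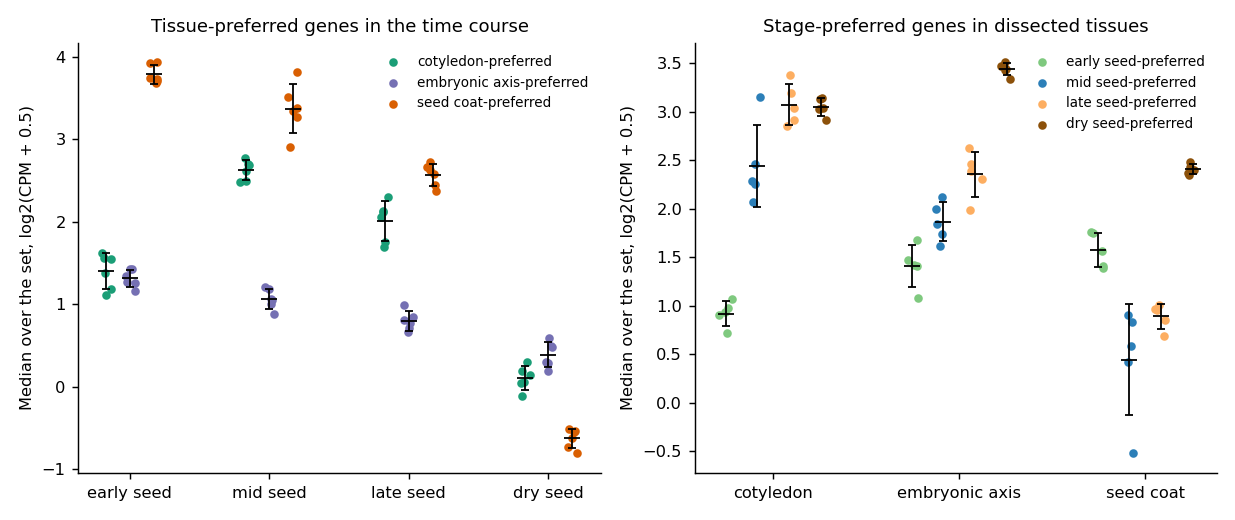
Median level of each gene set per library, as log2(CPM + 0.5), for tissue-preferred genes over the stages (left, 6 libraries per stage) and stage-preferred genes in the dissected tissues (right, 5 libraries per tissue), with 1 point per library and black bars for the mean and SD. The coat-preferred median goes from 3.79 in early seed to -0.62 in dry seed, and the late-preferred median is 3.08 in cotyledon and 0.89 in seed coat.

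Over the whole time course, 17479 of 18440 genes, or 94.8%, differed in at least 1 of the 3 consecutive comparisons and 4504 differed in all 3. In data simulated with no change, 0 genes did so by edgeR at an adjusted p under 0.05. Those data held no variation shared by the genes of a library, so they do not test for calls caused by it. Steady trends were less frequent than late reversals among rising genes: 397 genes rose in all 3 comparisons, and 642 rose into mid and late seed and then fell in dry seed. Among falling genes, 770 fell in all 3 comparisons and 344 fell into late seed and then rose in dry seed. Neighbouring comparisons share the mid-seed or late-seed libraries. With those libraries split so that no library entered more than 1 comparison, the counts were 229, 487, 543 and 214 genes in the same order, against 278, 334, 316 and 263 for independent lists.

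By mean share, 3 genes, chosen after their values were seen, were the most counted of all 8 groups. They led in every library of 6 groups, in 3 of 6 libraries of late seed and in 4 of 6 of dry seed. Sc18g0006960 led in early seed, with 4.86% ± 0.86 of counts, in mid seed, with 2.28% ± 0.35 (SD, n = 6), and in seed coat and whole seed, with 9.59% ± 0.44 and 4.86% ± 0.90 (SD, n = 5). In dry seed it had 0 counts, which allows a share of up to 1.92e-05% in the shallowest library, for counting error only. Sc03g0002590 led in late seed, with 3.98% ± 1.91 (SD, n = 6), and in cotyledon and embryonic axis, with 6.99% ± 1.00 and 13.5% ± 1.9 (SD, n = 5). Its share was 0.00680% ± 0.00427 in early seed and 0.0159% ± 0.0085 in dry seed. Sc24g0003280 led in dry seed, with 1.44% ± 0.45, and took 1.07% ± 0.47 in late seed and 0.00135% ± 0.00041 in early seed (SD, n = 6). Shares in the time course and in the dissection series were not tested against each other, since the series were counted and normalized separately.

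**Figure D3:**
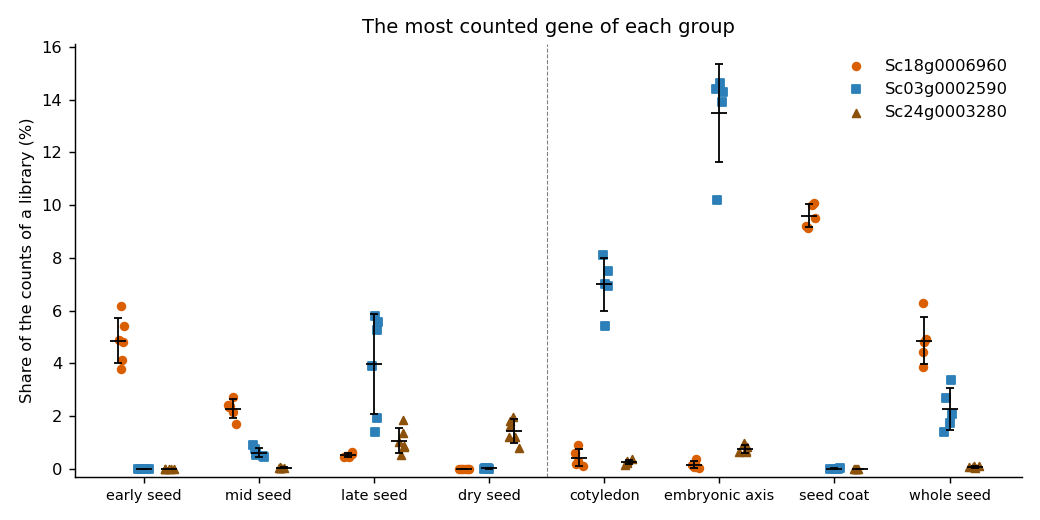
Share of each library's counts on the most counted gene of any group (percent, linear axis), 1 point per library with black bars for the mean and SD, 6 libraries per stage and 5 per tissue. Sc18g0006960 goes from 4.86% in early seed to 0 in dry seed and is at 9.59% in seed coat, and Sc03g0002590 is at 13.5% in embryonic axis.

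Cotyledon and embryonic axis, the parts of the embryo, differed in fewer genes than either did from the seed coat that surrounds them. Of 861 dry-preferred genes, 113 were higher and 259 lower in cotyledon, 489 did not pass, and their share of counts was 2.01% ± 0.07 in cotyledon and 3.31% ± 0.15 in axis (SD, n = 5). By camera in limma the dry-preferred set was lower in cotyledon (adjusted p = 0.00128), a call lost at adjusted p = 0.269 with an estimated correlation, and 7 of 40 splits of the libraries gave a p as small. Late-preferred genes took 16.7% ± 3.1 of cotyledon counts and 18.3% ± 2.5 of axis counts, an order that rested on 1 gene: without Sc03g0002590, left out after the values were seen, the shares were 9.74% ± 2.12 and 4.81% ± 0.90 (SD, n = 5). The set had 54 members higher and 32 lower in cotyledon out of 151. Of 225 early-preferred genes, 51 were higher and 79 lower in cotyledon. Of 64 mid-preferred genes, 27 were higher and 13 lower.

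By edgeR's test 8033 of 18499 genes differed between cotyledon and axis, 4241 higher and 3792 lower in cotyledon, and at least 2-fold 1793 and 1720. The balance turned with upper-quartile scaling (3916 and 4150) and with only the 2 groups compared (3674 and 3914). Sc05g0002950 and Sc18g0002680 were higher in cotyledon, at log2 differences of 7.72 ± 0.62 and 7.46 ± 1.00 (SE, edgeR adjusted p = 7.97e-09 and 4.99e-06). Sc16g0011600 and Sc11g0008890 were lower, at -8.21 ± 0.63 and -7.95 ± 0.52 (edgeR adjusted p = 3.17e-08 and 5.90e-10). The difference of Sc18g0002680 was 8.44 without axis library 2, and that of Sc16g0011600 was -9.45 without cotyledon library 5. Genes detected numbered 16261 ± 208 in cotyledon and 16853 ± 164 in axis (SD, n = 5; exact permutation test, two-sided, p = 0.00794, the smallest 5 libraries against 5 can give; adjusted p = 0.0119). By camera the early-preferred set was lower in cotyledon (adjusted p = 0.0323, and adjusted p = 0.489 with an estimated correlation). The mid-preferred and late-preferred sets did not pass (adjusted p = 0.139 and 0.273). The early-preferred call was lost without cotyledon library 4 (adjusted p = 0.126) or axis library 3 (adjusted p = 0.0600), and the mid-preferred set passed without cotyledon library 5 (adjusted p = 0.0266). With sets at 2-fold the early-preferred call was lost (adjusted p = 0.528) and the late-preferred set was higher in cotyledon (adjusted p = 0.0465).

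The seed coat was poor in the transcripts that marked mid and late seed and richer than cotyledon in those of early seed. By camera in limma, the late-preferred (adjusted p = 4.27e-08), mid-preferred (adjusted p = 1.04e-07) and dry-preferred sets (adjusted p = 0.0158) were lower in coat and the early-preferred set was higher (adjusted p = 1.40e-04). With an estimated correlation these calls were lost, at adjusted p = 0.122, 0.253, 0.381 and 0.253 in the same order. Of 151 late-preferred genes, 15 were higher and 90 lower in coat than in cotyledon, and they took 0.451% ± 0.015 of coat counts against 16.7% ± 3.1 of cotyledon counts (SD, n = 5). Of 64 mid-preferred genes, 2 were higher and 44 lower in coat. Of 225 early-preferred genes, 94 were higher and 25 lower, and of 861 dry-preferred genes, 160 were higher and 324 lower. Sc05g0005510 stood at 1131 ± 184 CPM in coat and 1.10 ± 0.77 in cotyledon (SD, n = 5), a log2 difference of 9.99 ± 0.54 (SE).

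In total 10716 of 18499 genes differed between seed coat and cotyledon by edgeR's test, 5228 higher and 5488 lower in coat, and at least 2-fold 2459 and 3000. Sc18g0007000 stood at 58.9 ± 7.5 CPM in coat and had 3 counts in all cotyledon libraries, a pooled ratio of 1380 (95% counting interval 472 to 6693). Sc08g0003300 and Sc02g0008030 had no count in any coat library and were at least 194-fold and 134-fold lower there than in cotyledon, against a floor of 3 counts per library. The highest edgeR adjusted p of the 4 named genes, which were chosen with p as a criterion, was 3.90e-08. The median level of the coat-preferred genes differed between the cotyledon libraries, from 0.77 to 1.78 on the log2(CPM + 0.5) scale.

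Seed coat and embryonic axis differed in more genes than the other pairs of dissected tissues. More dry-preferred genes were lower than higher in coat, with 161 higher, 408 lower and 292 not passing of 861, and their share of counts was 1.46% ± 0.04 in coat and 3.31% ± 0.15 in axis (SD, n = 5). By camera in limma the dry-preferred (adjusted p = 3.10e-04), mid-preferred and late-preferred sets (both adjusted p = 7.82e-04) were lower in coat, calls lost at adjusted p = 0.253, 0.291 and 0.253 with an estimated correlation. Late-preferred genes were mostly lower in coat, with 37 higher and 84 lower of 151, and so were mid-preferred genes, with 10 higher and 39 lower of 64. Early-preferred genes went both ways, with 97 higher and 60 lower of 225. Sc02g0008030 and Sc16g0011600 had no count in any coat library and were at least 320-fold and 189-fold lower there than in axis.

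Of 18499 genes tested, 11927 differed between seed coat and axis by edgeR, 5824 higher and 6103 lower in coat, and at least 2-fold 3122 and 3628. Coat against cotyledon came near this number, with 11712, when cotyledon libraries 1 and 5 were left out. Sc18g0003160 and Sc08g0004220 were higher in coat, at log2 differences of 10.50 ± 0.33 and 9.82 ± 0.58 (SE, edgeR adjusted p = 5.34e-15 and 8.25e-12). The difference of Sc08g0004220 was 10.45 without axis library 4. By camera the early-preferred set did not pass (adjusted p = 0.110), but it was higher in coat without coat library 3 (adjusted p = 0.0329) and with sets at 2-fold (adjusted p = 1.85e-06). By fry, which tests against no change and not against the other genes, it was higher in coat (adjusted p = 0.0132). Genes detected numbered 16066 ± 369 in coat, fewer than in axis (exact permutation test, two-sided, adjusted p = 0.0119) and not separable from cotyledon (adjusted p = 0.389). The 100 most counted genes took 29.4% ± 1.2 of coat counts, 32.7% ± 2.5 of axis counts and 36.8% ± 3.9 of cotyledon counts (SD, n = 5), and coat and cotyledon differed (exact permutation test, two-sided, adjusted p = 0.0238). That call was lost at adjusted p = 0.0714 without coat library 1, 2, 3 or 5, and coat and axis differed without axis library 3 (adjusted p = 0.0159). Coat and axis also differed for the 10 most counted genes (adjusted p = 0.0381) and a fixed list of 100 (adjusted p = 0.0190), and cotyledon and axis for 1000 genes (adjusted p = 0.0357, all by exact permutation test).

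Whole seed of the mid stage was fitted as a mixture of its dissected parts, in which seed coat took the largest mean share. The fitted shares of counts were 60.5% ± 7.5 for seed coat, 36.7% ± 9.4 for cotyledon and 2.83% ± 2.63 for embryonic axis (SD, n = 5). Seed coat ranged from 49.9% to 66.5% over the 5 libraries and cotyledon from 26.5% to 48.4%. These are shares of mRNA counts under the model, not of mass, and the weighted fit had a mean R2 of 0.897. The axis share was 1.78% without whole-seed library 2 and 4.70% with tissue-preferred genes only. Cotyledon lay above coat in whole-seed library 3 with tissue-preferred genes (48.3% and 45.7%) and without the 100 most counted genes (54.0% and 44.2%), and in library 4 in the latter (50.1% and 49.8%). Against cotyledon alone, whole seed was higher in Sc18g0007000, at 27.9 ± 6.6 CPM (SD, n = 5) against 3 counts in all cotyledon libraries, a pooled ratio of 655 (95% counting interval 223.7 to 3176).

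By edgeR's test 6136 of 18499 genes differed between whole seed and cotyledon, 3012 higher and 3124 lower in whole seed, and at least 2-fold 1242 and 908. The balance turned with no filter (3000 and 2837), with a replicate block (3012 and 2981), with only the 2 groups compared (2550 and 2545) and without cotyledon library 2, 3 or 4 or whole-seed library 1, 2 or 5 (without whole-seed library 1, 2725 and 2314). Sc18g0006990 was higher in whole seed, at 10.9 ± 3.6 CPM against 1 count in all cotyledon libraries, a pooled ratio of 749.6 (134.2 to 29633). Sc02g0004830 and Sc13g0004140 were lower, at log2 differences of -4.67 ± 0.58 and -4.48 ± 0.80 (SE, edgeR adjusted p = 6.47e-06 and 2.95e-04). The difference of Sc02g0004830 was -5.98 without whole-seed library 4. At least 16-fold, 5 genes were lower in whole seed, Sc02g0004830 and Sc13g0004140 among them. A fitted cotyledon share of 26.5% or more does not allow a fall that large, so the mixture does not hold for these genes. Whether the dissected parts and the whole seeds were in the same state was not tested.

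**Figure D4:**
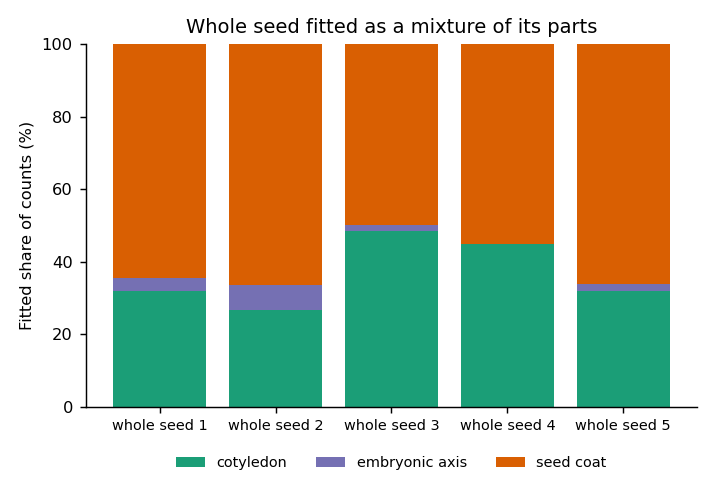
Fitted shares of counts (percent, stacked to 100) of cotyledon, embryonic axis and seed coat in each of the 5 whole-seed libraries, by non-negative least squares on the mean tissue profiles. Seed coat takes 49.9% to 66.5% and axis at most 7.003%.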

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

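The tests of depth and of carried-over tissue for the coat-preferred genes, and the tests of depth, scaling and seed coat RNA for dry against late seed, were chosen only after the result was seen. The test of carried-over tissue had 4 forms, each chosen after the outcome of the form before it, over 150 coat-preferred genes at 100 CPM or more in coat. In form 1 at most 33.3% of genes had an excess over cotyledon 4 within 2-fold of the median excess, under the bound of 50% for arguing against carry-over. In form 2, 12 to 31 of the genes lay below 0.5 of the level needed, which reached neither of its bounds. In form 3, limited to the 24 genes at 1000 CPM or more, the lowest share was 37.5%, over its bound of 25%. Form 4 counts genes below 0.5 of the level needed beyond counting error and the spread of the coat libraries, with a bound of 5% for arguing against carry-over. It was set for the 4 libraries together, was missed in 1 of them, and is therefore given per library. The test of scaling replaced an earlier form that was dropped as void after its outcome was seen. The test of seed coat RNA had 2 forms, with a bound, chosen after the values were seen, of a median under -1 and an upper quartile under 0 for arguing against it. Form 1 used the fitted log2 changes of all 212 cotyledon-preferred genes (median -3.44, upper quartile -0.31) and met the bound. Form 2, chosen after that outcome, set the 28 genes with no count in dry seed to their bound, since their fitted changes are not measured, and did not meet it.

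Coat-preferred genes stood at different levels in the 5 cotyledon libraries, with a median of 0.77 in cotyledon 4 and 1.78 in cotyledon 5 on the log2(CPM + 0.5) scale. The pattern was not particular to cotyledon: their median was 0.24 in axis 1 and 1.40 in axis 3. Depth was argued against: after thinning all libraries to the same total the highest and lowest cotyledon median still differed by 1.47. That value was taken without TMM scaling. The unthinned difference of 1.02 was taken with it, so the 2 values do not show what thinning alone changed. Coat tissue carried over in the proportions of the coat libraries was argued against as the whole cause of the typical excess in cotyledon 1, 2 and 5, where 13.3%, 10% and 18% of the genes were counted in form 4. In cotyledon 3 the share was 4.67%, so for that library carry-over and other causes cannot be told apart. The same share, taken against axis 1, was 8.67% in axis 2, 12.7% in axis 3, 2.67% in axis 4 and 10% in axis 5, with no prediction set for axis. A smaller carry-over, or one of part of the coat, stays open, as do differences between seeds, and no biological explanation was tested.

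Most tested genes, 14771 of 18440, differed between dry and late seed. Greater depth of the dry libraries was argued against, since 13862 genes differed after thinning all libraries to the same total. A scaling error shared by all genes was argued against as the whole cause, since no single shift of all log2 changes left under 42.3% of the genes at least 2-fold changed beyond their 95% interval. Less seed coat RNA in dry seed, for instance if the coat was removed, which the labels do not say, could account for the loss of coat-preferred genes, and the test of it was undecided: cotyledon-preferred genes also fell, 145 against 32 that rose, with a median log2 change of -2.74 with genes at 0 set to their bound, but the upper quartile was 0 in this form, -0.31 by the fitted values and 0.17 over the 184 genes with counts in dry seed, so these explanations cannot be told apart for that part. RNA loss during drying or storage was not tested, and the difference between the stages stays open beside it. The dry-seed libraries are named by another scheme than those of the other stages. Whether they were prepared or sequenced apart was not tested, and if so this could not be told apart from stage.

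Other splits of the libraries were set against each comparison, with 40 splits drawn from 462 possible in the time course and 126 in the dissection series, the real split included. For the number of genes that differed, 1 of 40 splits, the real one, gave as many in each of the 7 comparisons. This is the fewest that 40 splits can give, and it was not adjusted over the 7 comparisons. The other splits gave a median of 0 genes in each comparison. In each comparison at least 1 of them exchanged only 1 library between the groups. Such a split keeps much of the real contrast, which can raise the highest count among the other splits. The real counts and the highest of the other splits were 9142 and 3382 for mid against early seed, 10532 and 4040 for late against mid, 14771 and 8922 for dry against late, 8033 and 1599 for cotyledon against axis, 10716 and 5678 for coat against cotyledon, 11927 and 12 for coat against axis, and 6136 and 3855 for whole seed against cotyledon.

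For the gene sets the splits gave a different answer. In 2 of 21 set results only the real split gave a p as small, and in the other 19 other splits did too. With 40 splits and no adjustment over the 21 results, chance was not excluded for these 2 either. In brackets stand the unadjusted p of camera in limma for the real split and the lowest among the other splits. The 2 were the cotyledon-preferred set from early to mid seed (4.26e-09 and 4.07e-08) and the coat-preferred set from late to dry seed (9.72e-17 and 2.60e-15), each with 1 of 40 splits. The coat-preferred call was also lost with an estimated correlation (adjusted p = 0.0535). The coat-preferred set reached a p as small in 16 splits for mid against early seed (5.68e-08 and 2.15e-20) and in 13 for late against mid seed (3.22e-08 and 4.79e-19). The cotyledon-preferred set did so in 29 splits for late against mid seed (0.572 and 4.24e-04) and 7 for dry against late seed (1.01e-05 and 5.14e-08). The axis-preferred set did so in 9, 18 and 37 splits over the 3 comparisons in time order (0.0754, 0.260 and 0.941, with lowest others 0.00319, 1.83e-05 and 0.00648). Every other split mixes libraries of the 2 stages compared, so these counts do not show whether a set varies together within a stage. For the coat-preferred set camera's estimated correlation between genes, taken within groups, was 0.130, 0.129 and 0.121 in time order, where the preset was 0.01.

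In the dissection series the splits with a p as small were as follows, with the same values in brackets. For cotyledon against axis there were 12 for the early-preferred set (0.0242 and 6.46e-06), 26 for mid-preferred (0.127 and 2.88e-05), 21 for late-preferred (0.273 and 0.00358) and 7 for dry-preferred (7.47e-04 and 8.84e-06). For coat against cotyledon there were 4 for early-preferred (3.50e-05 and 7.91e-08), 2 for mid-preferred (1.74e-08 and 7.12e-09), 2 for late-preferred (3.56e-09 and 9.01e-10) and 4 for dry-preferred (0.0105 and 0.00633). For coat against axis there were 18 for early-preferred (0.0913 and 3.22e-04), 6 for mid-preferred (3.86e-04 and 8.77e-05), 8 for late-preferred (3.91e-04 and 2.68e-06) and 2 for dry-preferred (1.03e-04 and 2.30e-05).

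In 13 cases, out of 106 groups of values looked at, a single library lay far from the rest of its group. Chance gives about 1 in 20 groups, but this rate does not apply to 5 of the cases, where all other libraries were at 0 and the outcome was fixed, nor strictly to genes picked for their values. Among measures of whole libraries there were 3 cases in 35 groups, where chance gives 1.75. CPM on the 165 genes with ScUN identifiers were 41.8 in mid seed 2 (others 16.5 to 25.04), 252.3 in seed coat 4 (31.2 to 45.8) and 1502 in whole seed 4 (38.6 to 76.3). Sc03g0002590 took 10.2% of counts in axis 3 (others 13.9% to 14.6%). In TMM CPM, Sc09g0001520 stood at 79.8 in early seed 6 (others 0.996 to 12.3), Sc03g0000810 at 537.3 in dry seed 6 (83.7 to 229.0), Sc18g0002680 at 1.05 in axis 2 (0 to 0.302) and Sc02g0004830 at 3.38 in whole seed 4 (0.152 to 0.682). In the other cases the gene had counts in a single library of a group otherwise at 0: Sc14g0002460 in early seed 5 (0.107), Sc20g0004390 and Sc20g0000350 in late seed 3 (both 0.0679), Sc03g0000810 in late seed 4 (0.166) and Sc18g0006990 in cotyledon 5 (0.0565).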

How the results depend on the processing

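Thinning to the smallest total, leaving out cotyledon libraries 1 and 5, and leaving out late-seed libraries 4 and 6 were chosen only after seeing the data. Over 130 alternatives the numbers of genes that differed stayed within 0.779 to 1.36 times the reported numbers, with at least 81.9% of the smaller list shared in the same direction, and the 519 alternatives for named genes kept direction and side of the threshold. Settings in which a named gene was filtered out or had no adjusted p are not among these 519. Sc09g0001520 had 18 alternatives for mid against early seed, where the other named genes had 19. Thinning gave 8269, 9696, 13862, 7374, 10002, 11137 and 5584 genes in the order of the report. Without cotyledon libraries 1 and 5 whole seed against cotyledon gave 8329 and coat against cotyledon 11712. Without late-seed libraries 4 and 6 late against mid gave 9650 and dry against late 14587. With the replicate number as a block the counts were 8998, 10459, 14712, 7759, 10658, 11862 and 5993, but equal numbers did not pair the libraries: 1 of 36 and 6 of 30 such pairs correlated over 0.1. Of the genes that differed between mid and early seed, 52.5% were higher in mid seed under TMM and 44.2% under upper-quartile scaling. Depth limits the genes near the floor of 3 counts.

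With an estimated correlation, camera's adjusted p was 0.217 for the coat-preferred set in mid against early and late against mid seed, and 0.0535 for the coat- and cotyledon-preferred sets in dry against late seed. For cotyledon against axis it was 0.489 for the early- and 0.269 for the dry-preferred set. For coat against cotyledon it was 0.253 for the early- and mid-, 0.122 for the late- and 0.381 for the dry-preferred set. For coat against axis it was 0.291 for the mid- and 0.253 for the late- and dry-preferred sets. Fry tests a set against no change, not against the other genes. It passed for the axis-preferred set in time order (adjusted p = 5.64e-04, 0.00234 and 0.00395) and the early-preferred set in coat against axis (0.0132). With sets at 2-fold, camera's adjusted p was 0.528 for the early- and 0.0465 for the late-preferred set in cotyledon against axis and 1.85e-06 for the early-preferred set in coat against axis, and the axis-preferred set turned to higher in mid seed (0.903). Leaving out libraries moved camera's adjusted p from 0.0147 to 0.126 for the early- and 0.0266 to 0.481 for the mid-preferred set in cotyledon against axis, and 0.0329 to 0.129 for the early-preferred set in coat against axis. For the axis-preferred set in dry against late seed it ran from 0.932 to 0.999 and the direction turned in 6 of 12 cases, none near the threshold. The causes were not tested.

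For the share in the most counted genes, mid minus early seed was 1.19 (exact permutation test, adjusted p = 0.182), but -1.29 with 10 genes, the other direction (adjusted p = 0.0260), 3.61 with 1000 and 3.01 with a fixed list (both adjusted p = 0.00649). Dry minus late seed was -6.83, 1.21 (the other direction) and -6.02. Cotyledon minus axis was 5.93 with 1000 genes, and coat minus axis -3.74 with 10 and -4.12 with the fixed list. Without each library in turn, dry minus late ran from -4.40 to -1.35, coat minus cotyledon from -8.65 to -6.50 and coat minus axis from -4.23 to -2.65. Genes detected in mid minus early seed ran from -288.8 to -203.0, and coat minus cotyledon was 258.6 at 5 CPM, the other direction. At 2-fold, 99 genes rose throughout, 333 fell throughout, 184 rose and then fell in dry seed and 65 fell and then rose, as a stricter threshold leaves fewer genes. The other causes were not tested. The 24 alternatives for the mixture shares stayed within 1 SD. Leaving out 1 of 5 libraries cannot move a mean that far, so those alternatives were no test. Over the changes of setting the mean coat share ran from 56.3% to 65.8% and cotyledon from 32.0% to 40.9%. The axis share ran from 2.26% to 4.70%.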

Other observations

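The test on neighbouring identifiers was set before its result was seen, after neighbouring identifiers had appeared among the named genes. The rank correlations were chosen after seeing the data.

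Across 17872 genes measured in both series, stages and tissues were compared by rank correlation of mean levels, as a description, since genes are not independent and the series were normalized separately. Early seed had a rho of 0.884 with seed coat and 0.807 with cotyledon. Mid seed had 0.910 with whole seed, 0.893 with cotyledon, 0.859 with axis and 0.852 with seed coat. Late seed had 0.894, 0.902, 0.876 and 0.827 in the same order. Cotyledon and axis of the mid stage thus ranked nearer to late than to mid seed, and whole seed and seed coat nearer to mid seed. Whether the mid stage was the same in both series was not tested, which limits the sets carried between them. Dry seed had 0.694 with axis and 0.589 with seed coat. Coat-preferred genes took 0.450% to 1.83% of counts over the axis libraries and 0.625% to 2.77% over the cotyledon libraries.

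Genes next to each other in the order of their identifiers shared a tissue preference more often than shuffled orders gave. The order held the 18449 tested genes without the ScUN prefix, so genes that the filter left out can lie between neighbours. Of 1391 tissue-preferred genes, 129 adjacent pairs had the same preference, 73 for seed coat, 39 for axis and 17 for cotyledon, against a mean of 39.4 and a highest of 63 in 10000 shuffled orders (permutation p = 1e-04, the smallest these can give), a ratio of 3.27. Reads shared in full between near-identical neighbours were argued against as the whole cause. Only 14.0% of the pairs had log2 differences within 0.5 of each other in both contrasts. That bound makes no allowance for counting error in genes with few counts. Reads shared in part need not give equal differences, so such sharing stays open. A candidate explanation is that neighbouring genes are copies or are regulated together, which was not tested, and the sources used here do not state that identifiers follow position.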
